A study of Homo sapiens with 4 samples.

How the data were processed

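RNA sequencing was read for 4 libraries of SK-N-BE(2), an established human neuroblastoma cell line. Per the labels, 2 libraries came from cells given a short hairpin RNA against IGF2BP3 and 2 from cells given a control hairpin, here called shIGF2BP3 and shControl. Total RNA was extracted with TRIzol and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

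The authors deposited a table of whole-number counts per Ensembl gene, with 64252 genes and a column for each library. HISAT2 2.2.0, StringTie and the genome build hg38 are named in the submitters' processing notes, without their order or settings. The annotation release, the strand setting and the counting rule are not given in the sources used here. If StringTie made the deposited counts, they are estimates from coverage rounded to whole numbers. Antisense, overlapping, readthrough and near-identical genes are therefore uncertain, since their reads could have been split either way. Symbols were taken from a table of gene names for 56105 identifiers and from GENCODE release 29 for 486 more, while 7661 had none and held between 1.6% and 1.8% of the counts. Coordinates are those of GENCODE release 29 on GRCh38, the assembly also called hg38.

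The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its smallest count of 10, libraries were scaled by TMM, and shIGF2BP3 was compared with shControl by the robust quasi-likelihood test. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The design left 2 residual degrees of freedom, to which the shared prior added a median of 15.06, and the common biological coefficient of variation was 12.62%. Levels are TMM-scaled CPM (counts scaled to a common library total), as mean ± SD over 2 libraries, and fold changes are log2 with their standard errors (SE).

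Members of 36 gene lists were fixed before the data were examined, with 932 entries, of which 3 had no row in the table. Lists with at least 5 tested members were compared with all other tested genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera was also run with a correlation estimated for each list, and fry was run as a test that does not compare a list with other genes. Named genes followed a rule that was also fixed. It took IGF2BP1, IGF2BP2, IGF2BP3, E2F1, E2F2, E2F3 and MYCN, then the 10 highest and 10 lowest fold changes past the test with an average log2 CPM of at least 1 and groups that did not overlap. Clone-based names and pseudogenes were left out. It also took the 5 most abundant higher and 5 most abundant lower genes, and up to 4 members of each list by smallest p. Some genes that the rule takes are not reported here.

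The alternatives were other scalings, filters and tests (DESeq2 1.42.0, limma voom and an older edgeR fit), a replicate block, summed rows of the same symbol, a minimum fold change and leaving out each library. All were listed before the data were examined. The pipeline was tested on simulated counts for this comparison over 19161 genes. It recovered 29 of 67 genes changed 1.5-fold, 51 of 67 changed 2-fold and 63 of 66 changed 4-fold, with 10 false calls. The changed genes were drawn only from genes with counts well above the filter. A list simulated to fall by 1 on the log2 scale had an adjusted p of 1.96e-68 by camera. With an estimated correlation camera gave 0.0732, so that form had little power there. Genes were simulated independently, so the preset correlation was not tested for lists whose members move together. Among the lists camera called in the data, estimated correlations ran from -0.055 (E2F and RB family) to 0.612 (cytosolic ribosomal proteins). Where they are high, camera's p-values with the preset correlation may be too small.

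Total counts per library lay between 26755695 and 31946756. A count of 0 in a library allows a level of up to 3 counts, between 0.0958 and 0.111 CPM after scaling, which covers counting error only. Words in 3' UTRs were scanned with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 over 11339 protein-coding genes with a 3' UTR of at least 50 bases and an average log2 CPM of at least 2. Rank-sum z, mean shifts and Spearman's rho used fold changes with trends over GC content and log2 length of the scanned region removed. These trends were linear and squared terms fitted across genes. Medians are of fold changes without that step.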

Results

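RNA from SK-N-BE(2) neuroblastoma cells was sequenced with IGF2BP3 knocked down (shIGF2BP3, 2 libraries) or with a control hairpin (shControl, 2 libraries). IGF2BP3 is an RNA-binding protein that reads m6A, a methyl mark on mRNA. The series title places the comparison in the question of whether IGF2BP3 stabilises m6A-marked E2F2 mRNA. RNA stability and m6A were not measured in these libraries, which give RNA levels alone. Total counts were 27537200 and 26755695 in the shIGF2BP3 libraries and 27977019 and 31946756 in the shControl libraries. Replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of 7.15 within shIGF2BP3 and 8.48 within shControl, against 147.93 to 155.86 across the groups.

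IGF2BP3 fell in the knockdown, from 147.7 ± 12.49 CPM in shControl to 30.3 ± 2.26 CPM in shIGF2BP3 (SD, n = 2 each). Its counts were 813 and 875 in the shIGF2BP3 libraries and 4215 and 4347 in the shControl libraries. The gene (ENSG00000136231) lies on the minus strand of chromosome 7, from 23310209 to 23470467. Its log2 fold change was -2.28 (SE 0.09, adjusted p = 1.655e-12, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The paralog IGF2BP1 stood at 0.322 ± 0.0434 against 0.701 ± 0.269 CPM (log2 -1.08, SE 0.67) and did not pass the same test. IGF2BP2 had 5 and 0 counts in shIGF2BP3 and 4 and 2 in shControl, too few to test.

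E2F2, a transcription factor of the G1/S transition, fell from 76.97 ± 4.28 to 23.8 ± 1.24 CPM (SD, n = 2 each). The gene (ENSG00000007968) lies on the minus strand of chromosome 1, from 23506430 to 23531220. Its log2 fold change was -1.69 (SE 0.10, adjusted p = 1.32e-10, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). E2F1 fell by 1.45 and E2F3 by 0.61 on the log2 scale. MYCN, the oncogene amplified in this cell line, fell by 0.22 from 4742 ± 150.5 to 4074 ± 159.9 CPM. Its call ended without shIGF2BP3 replicate 2 (adjusted p = 0.0857, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

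**Figure D1:**
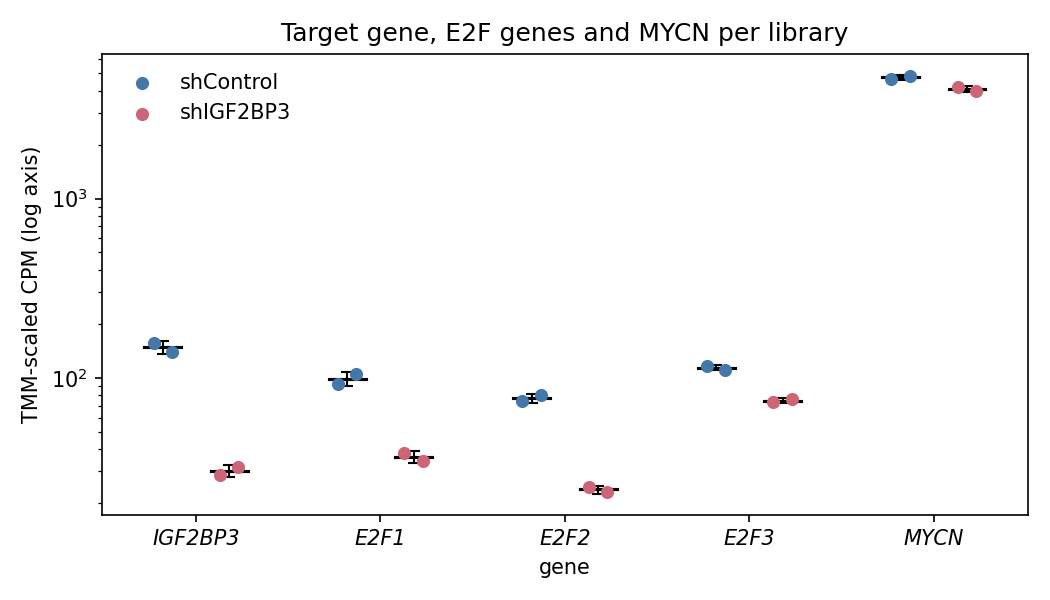
TMM-scaled CPM on a log axis for 5 genes, with a point per library, a bar at the mean of 2 libraries and whiskers of 1 SD. IGF2BP3 stood at 147.7 CPM in shControl and 30.3 CPM in shIGF2BP3, and E2F2 at 76.97 and 23.8 CPM.

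Across the transcriptome, 10178 of 19767 tested genes passed edgeR's quasi-likelihood test, 5120 higher and 5058 lower after knockdown. Of these, 2046 were at least 2-fold higher and 1810 at least 2-fold lower. Among 14096 protein-coding genes, 4183 were higher and 4405 lower. The groups did not overlap in 74.5% of tested genes, where chance gives 33.33%.

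Among the 10 highest genes, the collagenase MMP1 rose by 5.11 on the log2 scale from 1.11 ± 0.215 CPM in shControl, and TFPI2, a protease inhibitor, rose by 4.09 on the log2 scale. MMP3 had 0 counts in both shControl libraries and 13.9 CPM in shIGF2BP3, at least 125-fold higher against a floor of 3 counts per library. SCUBE1 reached 326.6 ± 4.09 CPM from 18.2 CPM (log2 4.17). HTR3B, APOB, GPNMB, NUPR1 and MYOF were also among them, between 6.26 and 4.21.

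Among the 10 lowest genes, INSM1, a transcription factor of neuroendocrine differentiation, fell by 3.74 and IL17RD, an antagonist of FGF signalling, by 3.71 on the log2 scale. The mitotic kinase PBK fell from 119.9 ± 4.80 to 9.34 ± 0.574 CPM (log2 -3.68, SE 0.11). GYG2, KCNMB4, FGFRL1, TOX3 and CACNG4 fell by 4.28, 3.77, 3.68, 3.67 and 3.61. The readthrough rows RPS10-NUDT3 and RPL17-C18orf32 are uncertain, since they share exons with RPS10 and RPL17. RPS10-NUDT3 had 0 counts in shIGF2BP3 and was at least 46.6-fold lower. RPL17-C18orf32 had 0 and 69 counts in the shIGF2BP3 libraries, and its call ended with DESeq2's Wald test (adjusted p = 0.2255). The call also ended without either shControl replicate, at a log2 fold change of -4.41 without replicate 1 and -4.64 without replicate 2.

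Among the most abundant genes past the test, MT-RNR2, MT-ND1, MT-ND2, MT-ND5 and VIM were higher by 0.19, 0.34, 0.27, 0.38 and 0.15 on the log2 scale. MT-ND4, MT-CO2, EEF2 and HSP90AB1 fell by 0.42, 0.54, 0.15 and 0.36, and MYCN was the fifth. The calls of MT-RNR2, VIM and EEF2 ended when single libraries were left out. Without shControl replicate 2 their adjusted p was 0.183, 0.305 and 0.201 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without shIGF2BP3 replicate 1 it was 0.0525, 0.257 and 0.0903, and without shIGF2BP3 replicate 2 it was 0.0910, 0.0781 and 0.250.

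Genes of the cell cycle fell together. All 48 members of the mitosis and G2/M list fell, with a median log2 fold change of -1.96, among them BIRC5 (-3.40), MAD2L1 (-2.49), PRC1 (-2.48) and CENPF (-2.05). In the G1/S and DNA replication list 47 of 48 fell and 1 did not pass, with a median of -1.53. Its members TK1 (-3.12), FEN1 (-2.33), PCNA (-1.85) and MCM2 (-1.70) make or copy DNA. Of 29 DNA repair genes 24 fell, 3 rose and 2 did not pass, with BLM at -2.18, XRCC2 at -1.91, EXO1 at -1.68 and FANCI at -1.65. Of 13 E2F and RB family genes 8 fell, 0 rose and 5 did not pass, and RBL2 fell by 1.26. The counts adjusted over the list alone were the same for these 4 lists. By camera the list had adjusted p = 5.08e-22 for mitosis, 4.44e-17 for G1/S, 1.37e-07 for DNA repair and 0.00295 for E2F and RB. These calls were lost at adjusted p = 0.373 with an estimated correlation, and 0.398 for DNA repair.

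**Figure D2:**
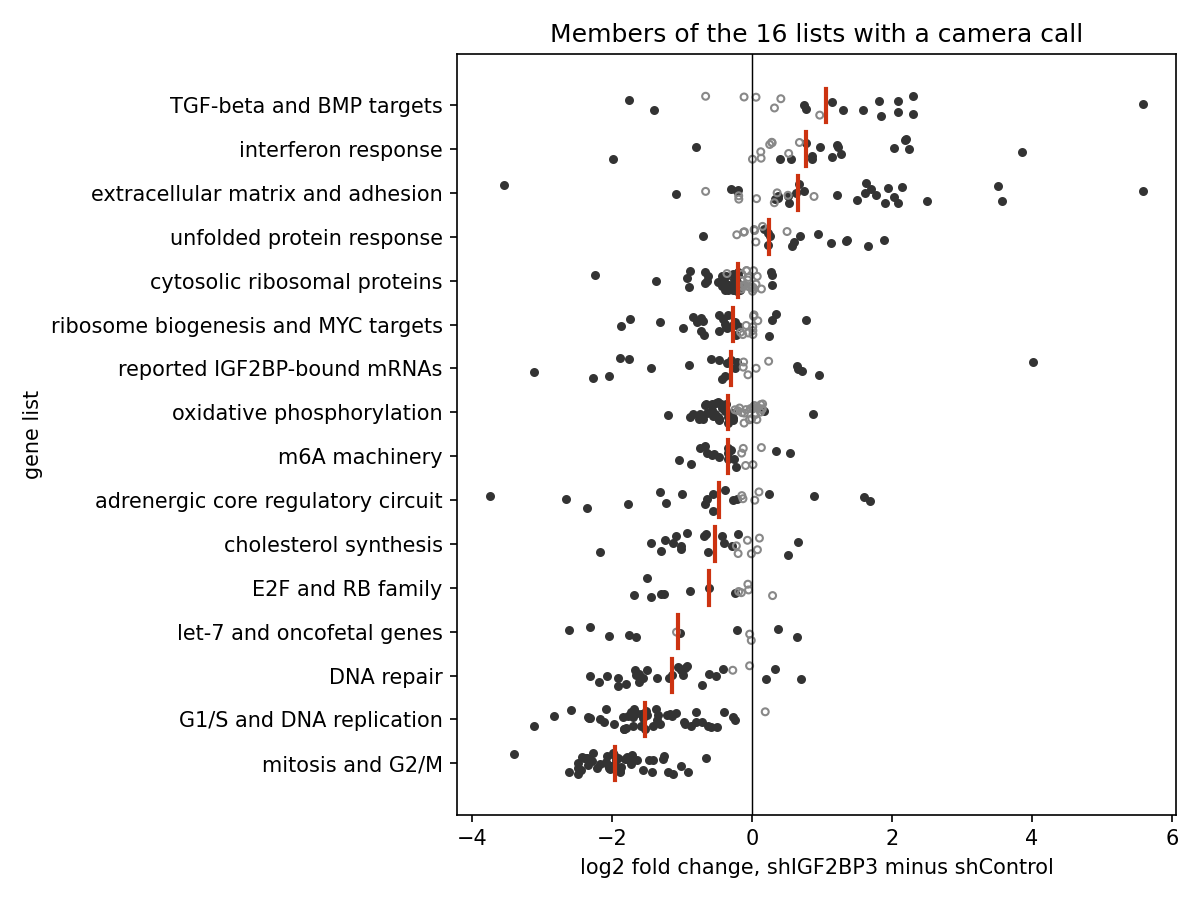
Log2 fold changes (shIGF2BP3 minus shControl) of the members of the 16 lists that camera called, with a point per gene, filled where the gene passed edgeR's quasi-likelihood test, and a vertical bar at the list median. The medians run from -1.96 for mitosis and G2/M to 1.05 for TGF-beta and BMP targets.

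Lists of the m6A machinery, of mRNAs reported to be bound by IGF2BP proteins and of oncofetal genes had more lower than higher members. Of 21 genes of the m6A machinery 14 fell, 2 rose and 5 did not pass, the same as adjusted over the list alone. METTL14, a subunit of the m6A methyltransferase, fell by 1.04, ELAVL1 by 0.88, HNRNPA2B1 by 0.74 and HNRNPC by 0.67. The list test, camera, gave adjusted p = 0.0096, and adjusted p = 0.398 with an estimated correlation. Of 25 mRNAs reported to be bound by IGF2BP proteins 15 fell, 5 rose and 5 did not pass (15 and 6 adjusted over the list alone). TK1 fell by 3.12, KIF2C by 2.27, PEG10 by 2.05 and FOXM1 by 1.88. The change of largest size in the list was a rise, that of MYC by 4.02 on the log2 scale, from 0.30 ± 0.15 to 4.82 ± 1.17 CPM (SD, n = 2 each), far below MYCN. Camera gave adjusted p = 0.0278, and adjusted p = 0.398 with an estimated correlation. This call ended without shIGF2BP3 replicate 2 (adjusted p = 0.0576 by camera), without shControl replicate 1 (0.0521) and without the low-count filter (0.0811). Of the 15 lower members 6 also stand in cell cycle, repair or E2F lists, and of the 19 members outside those lists 9 fell and 5 rose, with a median of -0.13 against -0.30 for the whole list. Of 12 let-7 and oncofetal genes 7 fell, 2 rose and 3 did not pass, the same as adjusted over the list alone. DLK1 fell by 2.62, CDC25A by 2.31 and H19 by 1.66. By camera the list had adjusted p = 0.0231, adjusted p = 0.398 with an estimated correlation, adjusted p = 0.0527 without shControl replicate 1 and adjusted p = 0.0597 without the low-count filter.

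Lineage factors of neuroblastoma moved in both directions. Of 22 genes of the adrenergic core circuit 14 fell, 4 rose and 4 did not pass (15 and 4 adjusted over the list alone). INSM2 fell by 2.66 and SOX11 by 1.78, while TBX2 rose by 1.68 to 637.6 ± 22.4 CPM. The list test, camera, gave adjusted p = 0.00988, and adjusted p = 0.398 with an estimated correlation. Of 19 noradrenaline and chromaffin genes 9 rose and 7 fell, with the transporter SLC6A2 at 1.72, DBH at 1.67, TH at -0.94 and CHGB at -0.87. Of 25 mesenchymal genes 14 rose and 5 fell, with CBFB at 1.65, NOTCH3 at -3.32, FOSL2 at -1.11 and TCF4 at -0.89. Of 36 neuronal and synaptic genes 21 rose and 9 fell (21 and 11 adjusted over the list alone), with SV2C at 2.39, SYT4 at 2.07, UCHL1 at -1.60 and TUBB3 at -1.39. Camera called none of the last 3 lists, with adjusted p = 0.738, 0.112 and 0.103, and for the first 2 of them the counts adjusted over the list alone were the same. Without the low-count filter it called the neuronal list higher (adjusted p = 0.0495).

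Matrix, TGF-beta, interferon and secretory stress genes were higher on balance. Of 36 matrix and adhesion genes 23 rose, 5 fell and 8 did not pass (24 and 5 adjusted over the list alone). The laminin LAMA4 rose by 3.52, TGFBI by 2.09 and MMP2 by 2.02, the last to 1864 ± 47.61 CPM. Camera gave adjusted p = 0.000225, and adjusted p = 0.373 with an estimated correlation. Of 20 TGF-beta and BMP targets 12 rose, 2 fell and 6 did not pass, the same as adjusted over the list alone. ID2 rose by 1.84 and SMAD6 by 1.82, and TGFBI is a member of both lists. By camera the list had adjusted p = 0.000934, and adjusted p = 0.373 with an estimated correlation. Of 25 interferon response genes 15 rose, 2 fell and 8 did not pass, the same as adjusted over the list alone. IFIT2 rose by 2.19, DTX3L by 1.26 and PARP9 by 1.23. The list test, camera, gave adjusted p = 0.00085, and adjusted p = 0.373 with an estimated correlation. Of 22 unfolded protein response genes 13 rose, 1 fell and 8 did not pass, the same as adjusted over the list alone. EDEM1 rose by 1.89, DNAJB9 by 1.66, SYVN1 by 1.36 and CREB3L2 by 1.12. Camera gave adjusted p = 0.00988, adjusted p = 0.543 with an estimated correlation, and adjusted p = 0.0544 without shControl replicate 2.

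Genes of sterol synthesis, ribosomes and respiration were lower on balance. Of 24 cholesterol synthesis genes 16 fell, 2 rose and 6 did not pass (17 and 2 adjusted over the list alone). FDFT1 fell by 2.18, HMGCS1 by 1.45, the regulator SREBF2 by 1.24 and SQLE by 1.14. By camera the list had adjusted p = 0.000934, and adjusted p = 0.373 with an estimated correlation. Of 56 cytosolic ribosomal protein genes 32 fell, 3 rose and 21 did not pass (35 and 3 adjusted over the list alone), with a median of -0.21. RPL34 fell by 2.25, RPS3 by 1.37, RPL23 by 0.94 and RPS25 by 0.89, and reads of such genes can be shared with pseudogenes. The list test, camera, gave adjusted p = 0.00085, and adjusted p = 0.592 with an estimated correlation. Of 35 ribosome biogenesis and MYC target genes 21 fell, 4 rose and 10 did not pass (22 and 4 adjusted over the list alone). FBL fell by 1.75, CDK4 by 1.32, ODC1 by 0.99 and HSPD1 by 0.85. Camera gave adjusted p = 0.00293, and adjusted p = 0.398 with an estimated correlation. Of 53 oxidative phosphorylation genes 30 fell, 2 rose and 21 did not pass (32 and 2 adjusted over the list alone). NDUFA4 fell by 1.20, NDUFB10 by 0.75 and ATP5MC3 by 0.68, while NDUFB5 rose by 0.88. By camera the list had adjusted p = 0.000963, and adjusted p = 0.543 with an estimated correlation.

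Growth arrest, death and stress genes were split, and camera called none of these lists. Of 29 CDK inhibitors and p53 targets 8 rose and 10 fell (adjusted p = 0.458), with CDKN1C at -1.98, CCNG1 at -1.90, CDKN2C at -1.32 and TP53I3 at 1.03. Of 27 apoptosis regulators 12 rose and 5 fell (adjusted p = 0.324 by camera), with DIABLO at 0.97, BMF at 0.72 and CYCS at 0.55. Of 29 genes of the ATF4 response 15 rose and 8 fell (15 and 10 adjusted over the list alone, camera adjusted p = 0.375), with NUPR1 at 4.26 and the serine synthesis enzymes PSAT1 at -2.38 and PHGDH at -0.86. Of 15 heat shock genes 2 rose and 5 fell (camera adjusted p = 0.642), with HSP90AA1 at -1.70 and HSPD1 at -0.85. Of 29 glycolysis and hypoxia genes 10 rose and 15 fell (camera adjusted p = 0.324), with SLC2A3 at 2.27 and P4HA1 at -1.45. Of 28 immediate early genes 11 rose and 7 fell (11 and 8 adjusted over the list alone, camera adjusted p = 0.336), with DUSP2 at 3.05 and ETV5 at -1.03. Of 14 antigen presentation genes 6 rose and 1 fell (camera adjusted p = 0.112), with NLRC5 at 1.22 and ERAP1 at 0.91. Where no other count is given, the counts adjusted over the list alone were the same.

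Of 15 Notch genes 4 rose and 9 fell (4 and 10 adjusted over the list alone, camera adjusted p = 0.13), with DLK1 at -2.62 and JAG2 at -1.74. Of 12 Wnt targets 3 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.52), with DKK3 at 1.37 and LGR5 at -1.04. MYC, at 4.02, is also a member of that list. Of 15 replication-dependent histones 2 rose and 4 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.375), and their mRNAs lack poly(A) tails. Of 9 nuclear RNAs 4 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.542), with MALAT1 at 0.68 and SNHG1 at -0.92.

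Camera called none of the lists of markers of other cell types. Of 8 Schwann cell and glia markers 2 rose and 2 fell (adjusted p = 0.95), with NGFR at 2.74 and ITGA8 at -2.69, and GFAP at 0 counts in shIGF2BP3, at least 4.98-fold lower. The list median was -0.27 with GFAP at its fitted value or at its bound. Of 11 fibroblast markers 4 rose and 2 fell (camera adjusted p = 0.375), with COL1A1 at 1.77, COL3A1 at 1.62 and LUM at -1.09. Of 6 epithelial markers 0 rose and 2 fell (camera adjusted p = 0.271, and 0.0496 without the low-count filter, a call). CLDN4 stood at -1.03 and KRT8 at -1.92, and their calls ended without single libraries, with adjusted p up to 0.130 and 0.200 without shControl replicate 1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The counts adjusted over the list alone were the same for these 3 lists. Leukocyte markers had too few tested members for a test.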

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

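Every alternative for which values are given here was chosen before the data were examined. IGF2BP3 and E2F2 were lower and past the test under all of them that give a value. IGF2BP3 lay between -2.39 and -2.20 and E2F2 between -1.75 and -1.64 on the log2 scale when single libraries were left out. The count of genes past the test was 8800 to 9442 without single libraries (4407 to 4648 higher, 4393 to 4807 lower), 8539 with DESeq2, 8757 without a low-count filter and 10028 with limma voom. Scaling by library size alone shifted the median of all genes from 0.0094 to 0.0897 and gave 5739 higher and 4405 lower. With a log2 fold change of at least 1 as a further condition, 3856 genes passed, 2046 higher and 1810 lower, by construction. The replicate block gave 10509 genes, and the deviations of libraries with the same number had a correlation of 0.021, so the numbers were not read as pairs. Camera called 4 lists higher and 12 lower, 3 to 4 and 10 to 12 without single libraries, and 5 and 11 without the low-count filter. With an estimated correlation it called 0 higher and 0 lower. Fry, which asks another question, called 11 higher and 17 lower. It gave Up for the Schwann cell and glia list (adjusted p = 0.024), where camera gave Down, and the cause was not tested. Among single named genes, 41 of the values under alternatives lost their call and 0 turned. They belong to VIM, EEF2, MT-RNR2, MYCN, RPL17-C18orf32, H2BC4, H2BC5, CLDN4 and KRT8. In the simulated data 43.3% of 1.5-fold changes were recovered. Far fewer genes were changed there than passed here, which made the adjusted threshold stricter, so that share may be too low for these data. The changed genes were drawn only from genes with counts well above the filter, so for low-count genes the share may instead be too high. A missing call still does not show that a gene was unchanged.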

Other observations

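The tests of motif matches in cell cycle transcripts, of base composition, of seed-type pairing and of readthrough rows were chosen only after the result was seen. The others were written down before their own result was seen. Those on GCTGTA and GTGCAATA concern words that scans of these same data had picked. RNAs of the mitochondrial genome did not move as a block. Of 22 mitochondrial tRNAs 13 were higher and 4 lower, both rRNAs were higher, and of 13 mRNAs 5 were higher and 3 lower by edgeR's quasi-likelihood test. MT-ND6 rose by 0.67 and MT-ND3 by 0.46 on the log2 scale, while MT-CO2 fell by 0.54. The mRNA list had no camera call (adjusted p = 0.911, 5 higher and 3 lower adjusted over the list alone).

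Lowered genes shared a short word in their 3' UTRs. Among 4096 words of 6 bases, GCTGTA had the lowest rank-sum z over 11339 genes, -13.99, against -4.82 as the lowest in 1000 permutations. The 3846 genes with it had a median log2 fold change of -0.10, and the others 0.01, so the shift per gene is small. Trends over GC content and length of the 3' UTR had been removed from the fold changes before they were ranked. The 177 arrangements of the same bases that share no run of 5 bases with it reached -4.51 at most. This argues against what those trends left of base composition or 3' UTR length as the source. AGCTGT, an arrangement that shares GCTGT with it, reached -11.54. Without all genes of the fixed lists the z was -14.35, which argues against members of those lists as its source.

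A candidate explanation is seed-type pairing of a small RNA that also matches IGF2BP3, such as the hairpin's product, whose sequence is not given in the sources used here. The mean shift grew from -0.241 (SE 0.024) with CGCTGT to -0.369 (SE 0.049) with ACGCTGT and -0.536 (SE 0.094, 75 genes) with ACGCTGTA. In coding sequences the shifts were -0.139 with CGCTGT, -0.233 with ACGCTGT and -0.432 (SE 0.111, 71 genes) with ACGCTGTA, so for the longest word the regions differ by no more than their errors. ACGCTGTA occurs in IGF2BP3 in the coding part of exon 9 of 15 (transcript ENST00000258729.7, chromosome 7, 23343833 to 23343840, minus strand, GRCh38), and 1.4% of the transcripts hold it. This series of words was put together after scans of 3 word lengths and after 23 forms around the core had been looked at, so its order is no independent test. The lowest word of 7 bases, TGCTGTA (z -11.76, 2007 genes), is absent from IGF2BP3, and ACGCTGT (415 genes) ranked 10 among words of that length. A z also depends on the number of genes, and the mean shift with TGCTGTA was -0.216 (SE 0.02), smaller in size than with ACGCTGT. Among the examined forms longer than ACGCTGTA, only GACGCTGTA occurs in IGF2BP3. It had a smaller shift than ACGCTGTA in 3' UTRs (-0.376, SE 0.211, 13 genes). In coding sequences its shift was larger (-0.521, 28 genes). The difference in 3' UTRs lies within its SE, so growth with the length of the match past 8 bases cannot be decided with so few genes. The word that extends ACGCTGTA by the next base of IGF2BP3 on its 3' side was not examined. AACGCTGTA (-0.885, SE 0.285, 14 genes) and ACGCTGTAA (-0.561, SE 0.195, 22 genes) had larger shifts in 3' UTRs than ACGCTGTA but are absent from IGF2BP3. Among the 23 forms 22 had a shift below 0, and ACGCTGTA itself ranked 25 among 61386 words of 8 bases (z -5.69, against -5.22 as the lowest in 100 permutations). E2F2 carries CGCTGT and GCTGTA once each, overlapping as CGCTGTA, in the coding part of exon 1 of 7 (chromosome 1, 23530648 to 23530654, minus strand). CGCTGTA also occurs in IGF2BP3, and genes with it in coding sequences had a mean shift of -0.215 (SE 0.049, 363 genes). Whether the fall of E2F2 owes anything to this match was not tested.

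The fall of the cell cycle lists was set against technical sources. With each library's trends over GC content and transcript length removed, the median of the 96 mitosis and G1/S members was -1.78 (SE 0.083), from -1.74 before, which argues against such a trend. The 39 members with neither GCTGTA nor CGCTGT had a median of -1.72 (SE 0.137), which argues against matches to these words in their own transcripts as the whole source. Members with other words of the same core, such as AGCTGT (z -11.54) and TGCTGT (z -11.27), were not left out, so matches to those words were not tested. An indirect effect of other lowered genes, and loss of IGF2BP3 itself, both stay open, since no further hairpin or rescue was analysed here.

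A further hypothesis was loss of IGF2BP3 at m6A-type motifs, in the 3' UTR alone or with the coding sequence. Under it, genes rich in the m6A-type word GGACT might fall more. Spearman's rho across genes, which are not independent replicates, was 0.006 for coding sequence with 3' UTR and -0.009 for 3' UTRs alone (SE 0.0094). The bounds set beforehand were below -0.05 for an effect and above 0 against it. The first value lies above 0 by less than its SE and the other between the bounds, so neither decides, and a word is a weak stand-in for measured m6A.

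Among 61386 words of 8 bases, GTGCAATA stood highest in raised genes (z 5.73, against 5.01 as the highest in 100 permutations). The 448 genes with it had a mean shift of 0.235 (SE 0.038). The word pairs with a seed that miR-92 shares with other microRNAs. MIR17HG, a host transcript of miR-92, fell by 0.93 on the log2 scale (log2 -0.93, adjusted p = 2.934e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, lower in both libraries). A lower level of such microRNAs may contribute, but 5058 of 19767 tested genes were lower, so the fall of MIR17HG is weak support. MicroRNAs were not measured. Host transcripts other than MIR17HG were not tested for this, so the word cannot be tied to a single host.

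Whether the readthrough rows among the lowest genes reflect how reads were assigned stays open. Summed with its parent, RPS10-NUDT3 changed by -0.294 and RPL17-C18orf32 by -0.158 on the log2 scale. Complete loss of the readthrough rows alone would have moved these sums by only -0.011 and -0.113, so the sums cannot decide between read assignment and a change in readthrough transcription.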
